A study of Mus musculus with 2 samples.

How the data were processed

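The samples are 2 total RNA libraries from E15.5 mouse intestine of strain B6NCrl, each from a separate pool of embryos of both sexes (78 and 62 embryos). Per the labels' protocols, RNA was extracted with the mirVana kit, fragments over 200 nucleotides were kept, 10 ng of RNA entered each library, ERCC spike-ins were added, and a manual for a SMARTer ultra-low-input kit is among the protocol documents. How ribosomal RNA was treated, the read length, the strand setting and the aligner are not given in the sources used here. The labels call the pools biological replicates 1 and 2, and this number was used as the replicate number.

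The authors deposited a gene table and a transcript table for each library, with the column layout that the quantifier RSEM writes. The name and version of their quantifier are not given in the sources used here. Per the readme deposited with the files, the assembly is mm10 and the annotation GENCODE M4. Per the file headers, the tables give expected counts, which the authors estimated per gene or transcript and which need not be whole because reads shared between genes are split. They also give TPM and FPKM per the file headers, both made by the authors from the estimated counts and effective lengths, with a maximum-likelihood and a posterior mean version of TPM. TPM is scaled over all entries, spike-ins included. The deposited bounds of a credibility interval for TPM were treated as a score without a stated level. Per the file headers, the transcript tables also give the percent of a gene's output that falls on each transcript. Each file belongs to 1 library, and no replicates were pooled by the authors.

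Of 69691 entries in a gene table, 43346 are Ensembl genes, 96 ERCC spike-ins, 1 the phiX genome and 26248 entries are named by a number alone. The last kind held 0.000163% and 0.000150% of the counts and was left out of every gene comparison with the spike-ins and phiX. Gene symbols, biotypes and positions came from GENCODE M21 on GRCm38, the same assembly, by Ensembl identifier without its version. A symbol was found for 42462 gene entries (98.0%), and the 884 others held 0.186% and 0.186% of gene counts. Totals were 34406900 and 40669800 estimated counts. Spike-ins took 2.16% and 1.76% of them.

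From the deposited values the following was computed. A gene was called detected at a TPM of at least 1 in both libraries. Ratios between libraries were taken as log2((TPM of replicate 2 + 1)/(TPM of replicate 1 + 1)), a scale that understates the change of low genes. The common biological coefficient of variation came from edgeR 4.0.16 on expected counts rounded to whole numbers after its expression filter (17590 genes), in R 4.3.3. DESeq2 1.42.0 supplied alternative size factors only. With 1 group, no differential test was possible. A chi-square test over genes with at least 10 counts in total asked whether the libraries differed beyond sampling noise.

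Before the data were examined, 50 gene lists for cell types, organs, pathways and cell states were fixed, with 701 entries. Of these 663 different genes were matched, and Muc16, Hbb-b1, Hbb-b2, Ahsp and Snhg1 were not analysed here. For 10 pairs of lists the difference of mean log2(TPM + 0.1), with TPM averaged over the libraries, was tested by a two-sided permutation test across genes, exact where a list had fewer than 10 members and with 100000 resamples otherwise. Their p-values were adjusted by Benjamini-Hochberg over the 10. For 44 lists with at least 5 members at a TPM of 1 in either library, the median ratio between libraries, minus the median of all detected genes, was placed among 10000 random lists of the same size matched in 20 expression bins. Globin shares, RNA class shares and the share of each transcript of 20 genes were averaged over the libraries.

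The genes named in the text follow a rule also fixed beforehand. It takes the 20 genes of highest mean TPM outside the spike-ins, the mitochondrial genome and annotated ribosomal RNA. For each list it takes the 4 highest members (all members of the smallest lists), every Hox gene with a TPM of at least 10 in both libraries, up to 4 members below a TPM of 1, and up to 2 members that differ over 2-fold. It takes the 10 largest ratios in each direction among genes with a mean TPM of at least 5 and 50 counts in either library, the 20 isoform genes, and ligands of the hedgehog, Wnt, BMP and Notch pathways. Some genes that this rule names are not reported here. To find near-identical copies, 31-base words (k-mers) of some genes were looked up in the M21 transcripts of all other genes on both strands. The genes searched were the 20 highest, those over 2-fold apart under these limits, and the Paneth and tuft, adult-type globin and ribosomal protein lists. Other named genes were not searched, so the lack of a stated copy for them says nothing about copies. This check was added after the values were seen.

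Alternatives covered the detection limit, unit, pseudocount, low-value filters, edgeR's TMM and DESeq2's scaling, posterior mean TPM, matching on length, overlapping list members and each library alone. Lists of acinar, islet, adrenal cortex, late enterocyte and caudal gut genes outside the fixed lists were written after the values of the fixed lists were seen. Scaling to spike-ins and a restriction to protein-coding genes were added after seeing the data. On simulated counts for 43346 genes with 200 genes lowered 2-fold, the list shift placed 20 of 20 lists of 10 changed genes outside the random range, with a median of -0.92, and 27 of 500 lists of unchanged genes. The simulated genes varied independently, so this does not cover lists whose members move together. For the list comparisons, 13 of 200 simulated pairs without a difference had a permutation p under 0.05. The edgeR step returned a coefficient of variation of 0.0994 where 0.1 was simulated (17688 genes). Further work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.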

Results

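Total RNA from mouse intestine at embryonic day 15.5 (E15.5) was sequenced in 2 libraries from strain B6NCrl, which form 1 group. Each library came from its own pool of mixed-sex embryos, 78 embryos in replicate 1 and 62 embryos in replicate 2. A value therefore averages over many embryos, and the spread between the libraries covers pooling, dissection and library preparation together. No second tissue, age or treatment was analysed here, so the comparisons are between sets of genes within the tissue and between the 2 libraries. The deposited tables hold 34406900 estimated counts for replicate 1 and 40669800 for replicate 2, of which 33665100 and 39953600 fall on mouse genes. At this depth 3 counts on a transcript of 1 kilobase correspond to a TPM of 0.125 and 0.107. Expression is given as TPM, as the mean ± SD of the 2 libraries (n = 2 throughout) or as the values of replicate 1 and replicate 2 in that order. Where genes are said to lead a list, the ranking is among the members of that fixed list. Gene positions are on assembly GRCm38 (mm10).

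Outside the mitochondrial genome and annotated ribosomal RNA, which this ranking leaves out, the most abundant transcripts came from the signal recognition particle, red cells, the cytoskeleton and translation. Rn7s1 and Rn7s2, the noncoding RNA of the signal recognition particle, headed the ranking at 12822 ± 889 and 12821 ± 889. Their sequences are identical over the 31-base words compared, so the split of reads between them is arbitrary. Among the adult-type globins, Hba-a2 reached 9374 ± 42.3, Hbb-bs 4719.5 ± 79.7, Hba-a1 3483 ± 167 and Hbb-bt 3463 ± 1.63. Beta-actin, Actb (ENSMUSG00000029580.10, chromosome 5, 142903115 to 142906754), stood at 5660.0 ± 409, the proline isomerase gene Ppia at 5098 ± 279, the ferritin light chain gene Ftl1 at 4858 ± 247 and the elongation factor gene Eef1a1 at 3806 ± 4.26. Rpl41 reached 3165 ± 126, the nuclear noncoding RNA Malat1 3013 ± 64.1, the actin-binding peptide gene Tmsb4x 2862 ± 477 and the histone gene Hist1h2ap 2593 ± 328. Gm42418, annotated as a long intergenic noncoding RNA, reached 4149 ± 46.0, and its closest sequence is CT010467.1. Ribosomal RNA was left out by annotated type alone, so ribosomal sequence under another type would remain in the ranking. Whether Gm42418 holds such sequence was not tested. Another 5 of the 20 highest genes hold the sequence of a more familiar gene and are uncertain as separate genes. These are Gm28437, which shares 100% of its words with mt-Co3, Gm28661 (100% with mt-Co2), Gm29216 (97.2% with mt-Co1), Gm10123 (100% with Ppia) and Gm22133 (100% with Ftl1). The sequences of Gm42418 (96.3%), Hist1h2ap (93.4%), Hba-a2 (92.6%), Hba-a1 (75.5%), Ftl1 (64.1%), Hbb-bt (59.4%), Hbb-bs (54.4%) and Eef1a1 (51.5%) also share over 50% of their words with other genes, so their single values are less certain than their depth implies.

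Of 43346 gene entries, 14986 reached a TPM of at least 1 in both libraries, and 13474 of these are protein-coding. Another 578 genes reached it only in replicate 1 and 414 only in replicate 2. A TPM of at least 10 in both libraries was reached by 8953 genes, 100 by 1635 genes and 1000 by 109 genes. Processed pseudogenes made up 454 of the detected genes, antisense genes 264 and long intergenic noncoding RNAs 197. Whether counting used the strand is not given in the sources used here, so it is unknown whether antisense values hold reads of the opposite strand.

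Ribosomal protein mRNAs took 6.91 ± 0.176% of all TPM, messenger RNAs of the mitochondrial genome 3.02 ± 0.289% and globin mRNAs 2.12 ± 0.00660%. The ERCC spike-ins, synthetic RNAs added in known amounts, took 4.18 ± 0.519%. Annotated ribosomal RNA, a class that includes the mitochondrial ribosomal RNAs, held 0.609 ± 0.0778%. Nearly all of it came from mt-Rnr1 and mt-Rnr2, which together stood at 6056 ± 807 TPM. The class share therefore says little about ribosomal RNA of the cytoplasm. The histone clusters held 0.377 ± 0.0372%. Within the mitochondrial genome, mt-Atp6 stood at 8061 ± 478, mt-Atp8 at 6206 ± 1323, mt-Cytb at 3150.4 ± 124 and mt-Nd1 at 2938 ± 95.2, and the ribosomal RNAs mt-Rnr2 and mt-Rnr1 at 4836 ± 756 and 1219.6 ± 51.1. Among the genes searched for copies, 4 nuclear pseudogenes have a mitochondrial gene as closest sequence (Gm28437, Gm28661, Gm29216 and Gm10925). They held a further 1.56 ± 0.0255% of TPM, which brings the mitochondrial messenger share to 4.58 ± 0.263% if they are counted with it. Other entries, such as Gm10222, which holds 98.9% of the words of mt-Nd4l, were not searched and may add to this share. Reads of mt-Co1, mt-Co2, mt-Co3 and mt-Atp6 may be split with the 4 pseudogenes, of which Gm28437 alone stood at 8574 ± 136. The order of single genes within the mitochondrial genome is therefore uncertain. Among the 11 replication-dependent histone genes of the fixed list, which leaves out Hist1h2ap, the highest were Hist1h4d at 292 ± 6.81 and Hist1h2bc at 126 ± 10.8. Hist1h1e stood at 42.8 ± 5.65 and Hist1h2ab at 33.3 ± 2.42.

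Epithelial genes were abundant. The structural genes had a median of 190.3 ± 5.16 TPM over 15 members, all detected in both libraries. Lgals4, a galectin of gut epithelium (ENSMUSG00000053964.12, chromosome 7, 28833854 to 28841708), reached 1278 ± 60.6, the tight junction gene Cldn7 848 ± 22.2, keratin Krt8 731 ± 33.7 and the adhesion gene Epcam 661 ± 11.3. All 20 transcription factors of the gut epithelium list were detected, led by Elf3 at 176 ± 1.73, Klf5 at 100.04 ± 6.52, the caudal-type homeobox gene Cdx1 (ENSMUSG00000024619.8, chromosome 18, 61018862 to 61036199) at 74.3 ± 4.57 and Hnf4a at 71.1 ± 0.170.

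Lipid-absorption genes of enterocytes were already abundant. The fatty acid binding genes Fabp1 (ENSMUSG00000054422.7, chromosome 6, 71199827 to 71205023) and Fabp2 stood at 2066 ± 208 and 612 ± 90.1, and the apolipoprotein genes Apoa1 and Apoa4 at 1388 ± 184 and 589 ± 151. Of the 16 early enterocyte genes, 15 were detected in both libraries and Clca4a was below a TPM of 1. In the fixed list of mature digestive enzymes, the highest were Alpi (intestinal alkaline phosphatase) at 102 ± 10.1 and the aminopeptidases Anpep and Enpep at 94.5 ± 8.14 and 82.2 ± 2.22. Sucrase-isomaltase Sis, Tmprss15, Treh and Arg2 were below a TPM of 1 in both libraries, 4 of 16 members. The early enterocyte list exceeded the mature enzyme list by 2.74 on the mean log2(TPM + 0.1) scale, in 2 of 2 libraries (two-sided permutation p = 0.039, Benjamini-Hochberg adjusted p = 0.0655 over the 10 list comparisons). This missed the threshold of 0.05, and with a pseudocount of 1 the difference of 2.38 had an adjusted permutation p of 0.0459 (0.0459 to 0.141 over the alternatives). Genes of a list are not independent replicates, so these p-values describe the spread of genes within the lists.

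Goblet and endocrine genes were expressed beside the absorptive ones. Tff3, the trefoil peptide of goblet cells (ENSMUSG00000024029.4, chromosome 17, 31125306 to 31129646), stood at 673 ± 111, Spink4 at 293 ± 48.1, the disulfide isomerase gene Agr2 at 222 ± 36.0 and the membrane mucin gene Muc13 at 196 ± 29.5. All 12 goblet genes were detected, and Zg16 differed by more than 2-fold between the libraries (23.6 and 6.41). The enteroendocrine list was led by the hormone genes Sct (secretin, 188 ± 30.8), Ghrl (ghrelin, 79.3 ± 9.48), Pyy (55.1 ± 10.2) and Gcg (proglucagon, 49.6 ± 7.23), with Insm1 below a TPM of 1. Of 14 Paneth and tuft genes 7 were below a TPM of 1 in both libraries, among them Defa5, Mmp7, Itln1 and Pou2f3. The alpha-defensin entries Defa24 and Defa17 were listed at 111 ± 17.1 and 82.2 ± 7.396, but 57.1% and 93.2% of their sequence words occur in other genes, so their identity is uncertain. Lyz1 stood at 11.8 ± 1.39 and shares 34.2% of its words with Lyz2, and Alox5ap at 7.77 ± 0.544. Stem and progenitor genes were detected throughout (15 of 15), with Smoc2 at 102 ± 6.80, Prom1 at 25.1 ± 1.25, Rnf43 at 12.0 ± 0.431 and Cd44 at 11.01 ± 0.7495. Early enterocyte genes lay 0.50 above goblet genes on the log2 scale in 2 of 2 libraries, a difference within the spread of the lists (permutation p = 0.70, adjusted p = 0.779).

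Smooth muscle and connective tissue genes were abundant. Smooth muscle actins Acta2 (ENSMUSG00000035783.8, chromosome 19, 34241090 to 34255590) and Actg2 reached 1274 ± 31.8 and 1081 ± 10.8, the myosin light chain gene Myl9 919 ± 3.59 and the tropomyosin gene Tpm2 427 ± 4.65. All 16 smooth muscle genes were detected. Collagen genes led the mesenchyme and matrix lists, with Col3a1 at 1399.8 ± 117, Col1a1 at 865 ± 66.1 and Col1a2 at 419.6 ± 34.7, followed by the intermediate filament gene Vim at 377 ± 10.7, and the matrix glycoprotein gene Sparc at 1374 ± 17.8. Only Thy1 of the 16 mesenchyme genes was below a TPM of 1, and all 18 matrix genes were detected. Genes of the interstitial cells of Cajal, the pacemakers of gut muscle, lay between 1 and 35 TPM, led by the connexin genes Gja1 (33.0 ± 2.58) and Gjc1 (30.2 ± 2.99), Etv1 (23.8 ± 3.24) and the chloride channel gene Ano1 (20.9 ± 2.13). Serosal mesothelium was represented by Krt19 (640.0 ± 17.1, also epithelial), Aldh1a2 (62.4 ± 1.39), Upk3b (55.6 ± 2.28) and Podxl (37.6 ± 0.0707). Smooth muscle genes exceeded Cajal genes by 2.65 on the log2 scale in 2 of 2 libraries (two-sided exact permutation p = 0.025, adjusted p = 0.0503). That value sits at the threshold: the adjusted permutation p was 0.0375 without replicate 2 and 0.0662 without replicate 1 (0.0375 to 0.0814 over the alternatives).

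Nervous system genes were lower than muscle genes. Uchl1 (ENSMUSG00000029223.9, chromosome 5, 66676091 to 66687234) stood at 72.5 ± 4.69, Stmn2 at 60.6 ± 5.53, the neuronal tubulin gene Tubb3 at 51.2 ± 2.45 and peripherin, Prph, at 37.0 ± 0.502. Of 22 enteric neuron genes 20 were detected in both libraries, while Nos1 and Chat, which make nitric oxide and acetylcholine in mature neurons, were below a TPM of 1. Among glial and neural crest genes, the endothelin receptor gene Ednrb reached 106 ± 14.3, Fabp7 41.4 ± 6.02, Erbb3 25.9 ± 0.693 and Nes 15.3 ± 1.87, and Gfap and Sox2 were below 1. Smooth muscle genes exceeded enteric neuron genes by 3.14 on the log2 scale in 2 of 2 libraries (permutation p = 0.0002, adjusted p = 0.001).

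Vessels, macrophages and red cells were all present. Egfl7 (98.9 ± 6.07), Plvap (64.2 ± 1.73), Eng (52.5 ± 0.0919) and Esam (40.2 ± 1.17) led the blood endothelium list, in which all 16 genes were detected. Lymphatic genes were led by the chemokine gene Ccl21a at 73.5 ± 0.431, Nrp2 at 24.7 ± 1.78, Pdpn at 21.8 ± 1.72 and Lyve1 at 12.1 ± 2.12, and mural cell genes by Anpep (also in enterocytes), Kcnj8 at 36.1 ± 2.55, Pdgfrb at 25.2 ± 0.523 and Cspg4 at 10.2 ± 0.0354, with Higd1b below 1. Of 14 macrophage genes 13 were detected, with Lyz2 at 88.0 ± 4.67, C1qb at 56.7 ± 0.622, Tyrobp at 47.3 ± 7.96 and C1qa at 45.3 ± 4.84, and Cd163 was below 1. Among other leukocyte genes Id2, which many cell types express, stood at 328 ± 55.6, platelet factor Pf4 at 41.5 ± 0.0424, and the neutrophil genes S100a8 and S100a9 at 41.3 ± 11.9 and 20.1 ± 7.73. The lymphocyte genes Cd3e, Cd3g and Il7r were below a TPM of 1, among 6 of 15 members.

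Embryonic globins made up 0.981 ± 0.310% of globin TPM, so nearly all globin message was of the adult type. Hbb-y (ENSMUSG00000052187.3, chromosome 7, 103851749 to 103853216) was listed at 130.3 and 212 in replicates 1 and 2, Hba-x at 30.3 and 40.6 and Hbb-bh1 at 1.62 and 1.81. By counts the embryonic share was 0.886% in replicate 1 (95% Wilson interval 0.850 to 0.923%) and 1.38% in replicate 2 (1.34 to 1.43%). The libraries therefore differed by more than counting error. Reads were amplified without molecular identifiers as far as the sources used here tell, so such intervals cover counting error only.

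Genes of neighbouring organs were compared with the epithelial regulators to describe what else the dissected tissue held. Pancreatic enzyme genes were high and unequal: chymotrypsinogen Ctrb1 (ENSMUSG00000031957.5, chromosome 8, 111686519 to 111691010) was at 2585 and 949.8 in replicates 1 and 2, amylase Amy2a5 at 1641 and 546, and the carboxypeptidase gene Cpa1 at 525 and 223. Amy2a5 shares 62.3% of its sequence words with other genes, chiefly its copies, so its own value is uncertain. Cela2a (476 and 111) and Prss2 (140.4 and 37.2) differed most between the libraries within this list, and Pnlip was below a TPM of 1. Liver genes were led by Cps1 (275 ± 5.51, also an enzyme of fetal enterocytes), transferrin Trf (236 and 160.4), Afp (190.0 and 143) and Apoa2 (102 and 70.8), with Tat, Cyp2e1 and Fetub below 1. Stomach genes were low: Muc1 was at 16.4 and 8.62, Tff1 at 6.83 and 7.75, Tff2 at 6.45 and 2.07 and Cldn18 at 4.03 and 2.01, and 9 of 15 members, such as Sox2, Gkn1, Gkn2 and Gkn3, were below 1. Epithelial regulators exceeded stomach genes by 4.86 on the log2 scale in 2 of 2 libraries (permutation p = 2e-05, the smallest that 100000 resamples give, adjusted p = 0.0002). The difference fell to 3.59 with a pseudocount of 1 and to 3.72 without members under a TPM of 0.5. Epithelial regulators lay 1.04 above liver genes (permutation p = 0.22, adjusted p = 0.270) and 1.12 below pancreas genes, a difference of -1.12 (permutation p = 0.20, adjusted p = 0.270), each in 2 of 2 libraries and within the spread of the lists. Replicate 1 alone gave -1.53 against pancreas genes and replicate 2 alone -0.49.

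Other organs contributed little. Of 10 lung genes 8 were below a TPM of 1, among them Sftpc, Sftpb, Sftpa1 and Sftpd, and the highest were Etv5 at 9.46 ± 0.198 and Ager at 2.38 ± 0.212, which are not confined to lung, followed by Foxj1 at 0.595 ± 0.0636. Of 12 kidney, gonad and adrenal genes 10 were below 1 in both libraries, such as Six2, Pax2, Pax8, Lhx1 and Nr5a1, and the exceptions were Hsd3b1 at 12.9 and 1.10 and Nphs1 at 2.99 and 0.930, both over 2-fold higher in replicate 1. Spleen mesenchyme genes included Bcl11a at 15.4 ± 1.47, Wt1 at 10.3 ± 0.0495 and Nkx3-2 at 2.30 ± 0.134, whereas Tlx1 and Nkx2-5 were at 0.105 ± 0.0212 and 0.0850 ± 0.0495. In the list of skeletal muscle and bone, 7 of 14 genes were below 1, such as Myod1, Myog, Pax3 and Pax7, and alpha-actin Acta1 was at 5.19 and 18.3, with Ckm at 4.92 ± 1.58, Tnni2 at 3.54 ± 0.283 and Col2a1 at 2.08 ± 0.205.

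**Figure D1:**
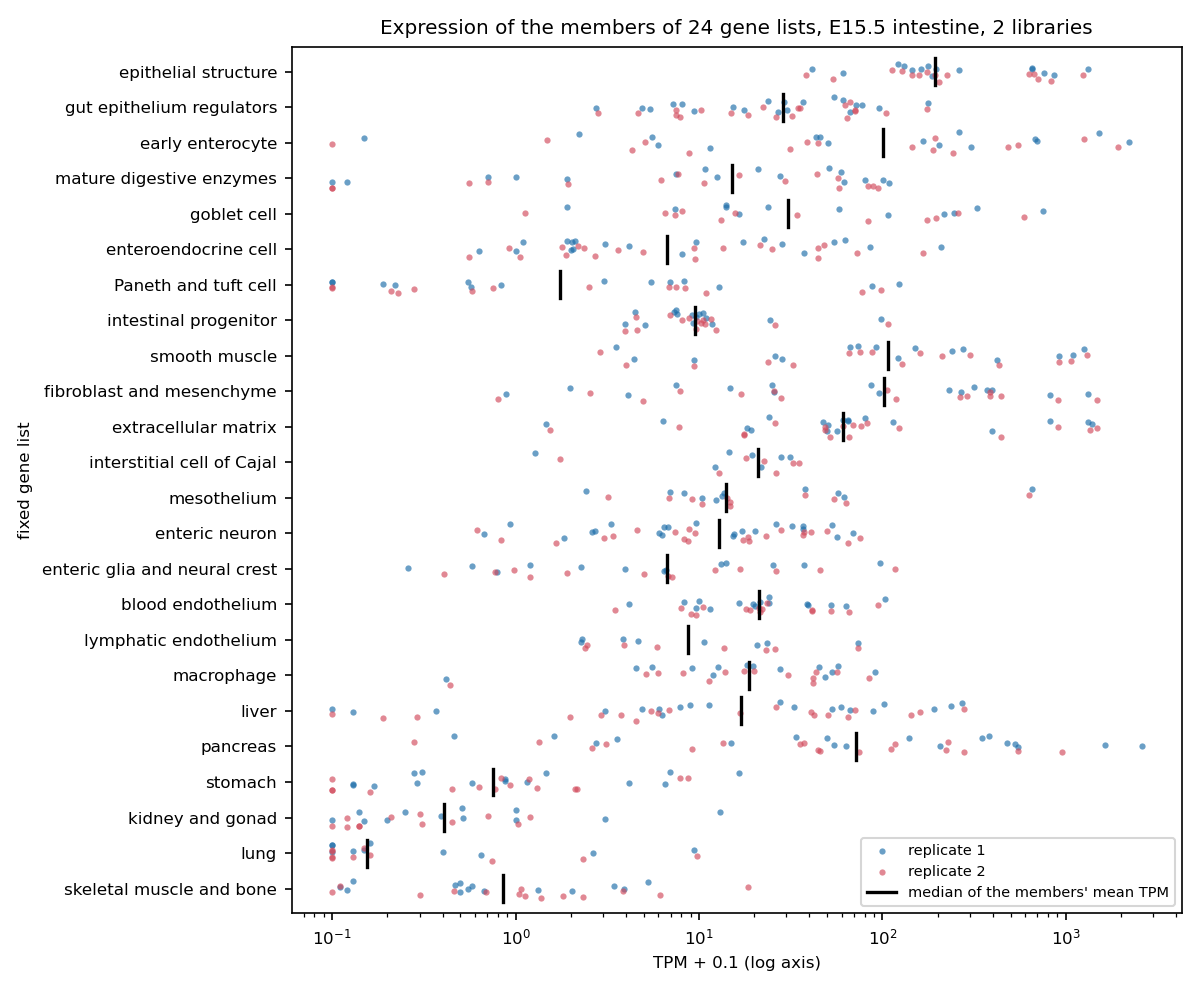
Expression of each member of 24 gene lists in replicate 1 (blue) and replicate 2 (red), as TPM + 0.1 on a log axis, with a black bar at the median of the members' mean TPM. Epithelial structure, smooth muscle, mesenchyme and early enterocyte lists have medians near or above 100, and lung and kidney lists lie mostly below a TPM of 1.

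For position along the gut, Hox genes, whose expression follows the body axis, and fixed lists of proximal and distal intestinal genes were examined. No regional sample was analysed as a reference, so levels of different genes do not measure the share of each region. Hoxb5 (ENSMUSG00000038700.4, chromosome 11, 96303336 to 96306121) was the highest Hox gene at 24.4 ± 2.58, followed by Hoxa5 at 20.0 ± 1.37, Hoxd3 at 15.8 ± 0.354 and Hoxb2 at 15.6 ± 1.35, with Hoxb1 and Hoxd1 below a TPM of 1. In groups 6 to 9, Hoxb6 stood at 12.7 ± 0.948, Hoxb7 at 9.66 ± 1.05, Hoxa7 at 8.38 ± 1.33 and Hoxc8 at 5.53 ± 0.488. In groups 10 to 13, Hoxa10 was at 9.43 and 16.9, Hoxd10 at 4.01 and 6.62, Hoxb13 at 2.99 and 1.94 and Hoxa11 at 1.69 and 2.78, and 6 of 12 genes, among them Hoxa13, Hoxc11, Hoxc12 and Hoxc13, were below a TPM of 1. Groups 6 to 9 exceeded groups 10 to 13 by 2.01 on the log2 scale in 2 of 2 libraries (permutation p = 0.013, adjusted p = 0.0324). The adjusted permutation p rose to 0.0581 without replicate 1 and to 0.166, for a difference of 0.96, when members under a TPM of 0.5 were left out (0.0205 to 0.166 over the alternatives). Groups 6 to 9 and groups 1 to 5 differed by 0.06 (permutation p = 0.93, adjusted p = 0.935).

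Genes of the proximal list exceeded those of the distal list, which does not by itself measure the regional mix of the tissue. Besides Fabp1 and Sct, the proximal list held the endodermal factor Gata4 at 36.2 ± 0.764 and cholecystokinin, Cck, at 26.7 ± 2.45. The distal list held Osr2 at 25.2 ± 2.40, Hoxb13 and the mucin gene Muc4 at 1.74 ± 0.431, and Hoxd13, Hoxa13, Slc10a2 and Car1 were below a TPM of 1. The lists differed by 3.68 on the log2 scale in 2 of 2 libraries (two-sided exact permutation p = 0.0088, adjusted p = 0.0294). Of the 8 proximal genes 7 also stand in another list, so this comparison is not independent of the epithelial and endocrine values above.

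**Figure D2:**
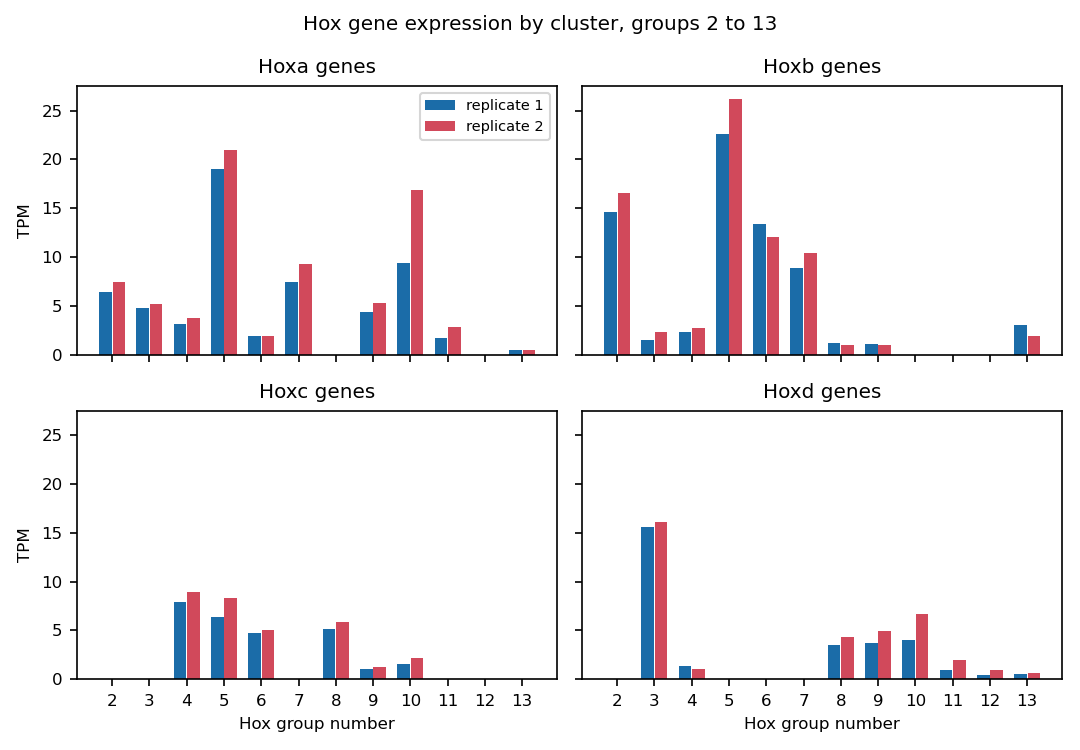
TPM of Hox genes of groups 2 to 13 by cluster (Hoxa to Hoxd, panels) and group number (horizontal axis), with bars for replicate 1 (blue) and replicate 2 (red). Hoxb5 and Hoxa5 are the highest, and Hoxa10 is at 9.43 and 16.9 in replicates 1 and 2.

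Signalling genes were detected for most pathways. Among hedgehog genes, of which all 14 were detected, the co-receptor gene Gas1 stood at 71.6 ± 9.52, the epithelial ligand gene Ihh at 25.0 ± 1.27, Smo at 23.4 ± 0.467 and the receptor gene Ptch1 at 20.9 ± 0.0354, and the second ligand gene Shh at 6.53 ± 1.46. Wnt modulators Sfrp2 (84.5 ± 9.32) and Sfrp1 (60.4 ± 4.99) exceeded the ligand gene Wnt5a (21.2 ± 2.58), and Dkk3 (22.1 ± 0.785) lay within its spread, and Wnt2, Wnt3, Wnt6 and Wnt9b were among 5 of 26 genes below a TPM of 1. BMP target genes Id2, Id3 (231 ± 10.9) and Id1 (90.6 ± 8.79) were high, and the ligand genes Bmp4, Bmp7 and Bmp2 stood at 52.8 ± 6.02, 16.5 ± 2.80 and 12.7 ± 1.67. For Notch, Hes6 was at 82.1 ± 4.66, Hes1 at 51.4 ± 7.23 and the ligand genes Dll1 and Jag1 at 18.3 ± 1.43 and 14.2 ± 1.53, with all 16 members detected. Retinoid and growth factor genes were led by the retinaldehyde dehydrogenase genes Aldh1a1 (69.5 ± 1.90) and Aldh1a2 and by Fgfr2 (58.3 ± 1.86), and Fgf7 was below 1.

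Cell cycle and imprinted genes were abundant. All 22 cell cycle genes reached a TPM of 10 in both libraries, led by Cdk4 at 1317 ± 17.97, Cdk1 at 355 ± 15.5, Birc5 at 268 ± 18.4 and Pcna at 211 ± 8.35. Imprinted genes were high, with the noncoding H19 at 1025 ± 106, Igf2 at 802 ± 13.8, Mest at 589.7 ± 28.3 and Cdkn1c at 396 ± 8.10, while Lin28a and Lin28b were below 1. Rapid-response genes were moderate, led by Myc (86.3 ± 5.32), Jun (71.8 ± 3.37), Ier2 (70.8 ± 1.20) and Ccn1 (41.0 ± 1.73), with Fosb, Egr2 and Egr3 below 1. Chaperone genes were led by Hspa8 (2066 ± 98.2), Hsp90aa1 (754 ± 42.3), Hspe1 (687 ± 78.9) and Hspd1 (601 ± 25.2), and the inducible Hspa1b was below 1. Among the 21 ribosomal protein genes of the fixed list, which leaves out Rpl41, the highest were Rpl32 at 1918 ± 163, Rps14 at 1637 ± 18.1, Rps18 at 1539.9 ± 67.7 and Rplp0 at 1347 ± 14.2. The noncoding Gas5 stood at 499 ± 9.72, and Terc and Rny3 were below 1. In these pools of both sexes, Xist stood at 18.2 and 16.3, and the Y-linked genes Eif2s3y at 24.01 and 32.3, Ddx3y at 17.5 and 20.6, Uty at 8.97 and 8.87 and Kdm5d at 6.57 and 8.10.

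The 2 libraries were close but not identical. Across the 14986 detected genes, which are not independent replicates, Pearson's r of log2(TPM + 1) was 0.993 and Spearman's rho 0.992. The median absolute log2 ratio between libraries was 0.11 and its 95th percentile 0.41, and 104 genes differed by more than 2-fold. That count was 56 for genes at a TPM of 5 or more, 59 for protein-coding genes and 365 without a filter. The common biological coefficient of variation from edgeR was 9.70%. Counts differed by more than sampling noise (chi-square per degree of freedom 18.3 with 19731 degrees of freedom over genes with at least 10 counts in total). The test covers counting error only, and the labels alone give the libraries as separate pools.

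Genes higher in replicate 1 included enzymes of the adrenal cortex and the exocrine pancreas. Among 11297 genes with a mean TPM of at least 5 and at least 50 counts in either library, 62 were over 2-fold lower in replicate 2 on the log2(TPM + 1) scale and 20 over 2-fold higher. Of the lower genes 47 were protein-coding. Akr1b7 (ENSMUSG00000052131.7, chromosome 6, 34412334 to 34423142) was at 36.3 and 2.06 in replicates 1 and 2, the steroid hydroxylase genes Cyp21a1 and Cyp11b1 at 15.01 and 0.320 and 10.9 and 0.270, Hsd3b1 at 12.9 and 1.10, and the milk-clotting protease gene Cym at 111 and 9.52. The other 5 of the 10 largest differences in that direction belong to Rnu3b1, Rnu3b3, Gm2260 and Gm10233, whose sequence words all occur in other genes, and to ENSMUSG00000103057.1, an entry without a symbol (38.1 and 6.38 TPM). The 10 largest in the other direction were Gm4294, Gm2274, Gm15432, Gm26602, Gm13304, Gm10243, Rpl35a-ps6, Rpl35a-ps4, Rpl35a-ps3 and Rnu3b2. Each shares over 50% of its sequence words with another gene, and 9 of them were listed at 0 in replicate 1. Among the 62 lower genes, mt-Nd4l was at 79.2 and 31.4 and shares 98.9% of its words with Gm10222. The small RNA gene Rny1 was at 0 and 5.51.

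**Figure D3:**
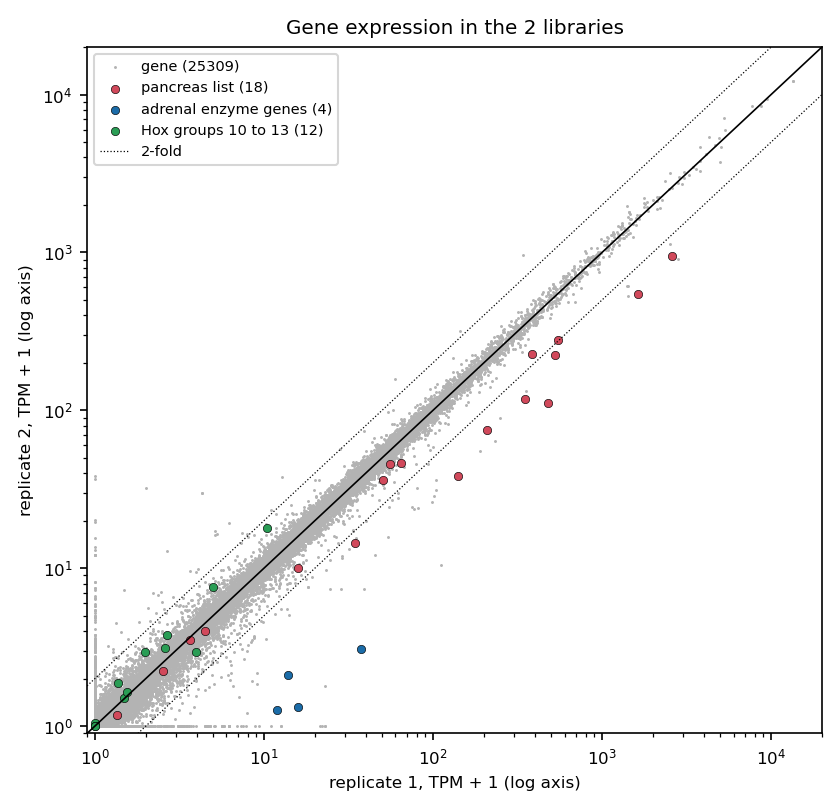
TPM + 1 of each gene in replicate 1 (horizontal) and replicate 2 (vertical), both on log axes, with lines of equality and of 2-fold difference. Members of the pancreas list (red) and 4 adrenal enzyme genes (blue) lie on or below the line of equality, and Hoxa10 (green, 9.43 and 16.9) lies above it.

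Shifts of whole lists between the libraries were set against 10000 random lists matched on expression. The pancreas list was lower in replicate 2 by the largest amount, a median log2 ratio of -0.99 for 17 members, all 17 of them lower. Liver genes (-0.50, 16 of 17 lower), stomach genes (-0.48, 4 of 6), goblet genes (-0.36, 11 of 12), early enterocyte genes (-0.32, 15 of 15), mature enzymes (-0.21, 10 of 12) and Paneth and tuft genes (-0.20, 5 of 7) also lay below the central 95% of random lists. Above it lay Hox groups 10 to 13 (0.51), skeletal muscle and bone (0.35), replication-dependent histones (0.24), X-inactivation and Y-linked genes (0.20), interstitial cells of Cajal (0.18), fibroblast and mesenchyme (0.15), enteric neurons (0.14), Hox groups 1 to 5 (0.14) and the mitochondrial genome (0.11). These 16 of 44 lists compare with 2.2 expected for lists of genes drawn independently. Members of a cell type or organ list can move together, and some lists share members, so 2.2 may be too low for them. The shifts describe these 2 libraries only. Epithelial regulators (-0.01), smooth muscle (-0.02), cell cycle (0.06) and red cell genes (-0.02) stayed within the random range. The X-inactivation and Y-linked list moved inside the range under edgeR's and DESeq2's scaling, and the stomach and Paneth lists did so when undetected members were added. The same addition lowered the shift of Hox groups 10 to 13 to 0.16 (4 of 12 lower), still above its range. The skeletal muscle and bone shift was 0.63 with a pseudocount of 0.1 and 0.23 with spike-in scaling, above its range in both.

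**Figure D4:**
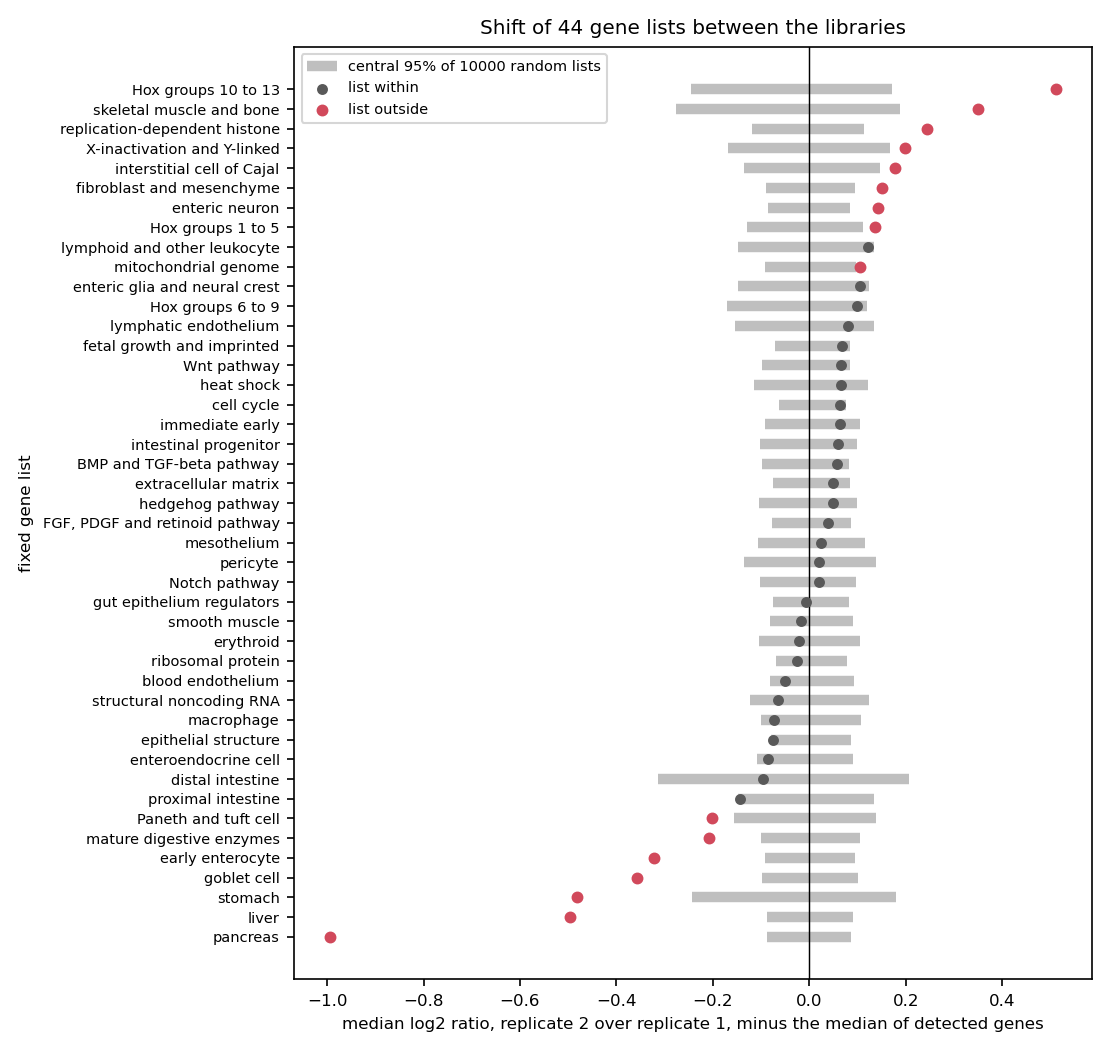
Median log2 ratio of replicate 2 over replicate 1 for members of 44 gene lists at a TPM of 1 or more in either library, minus the median of detected genes, with grey bars for the central 95% of 10000 random lists matched on expression. Red points mark the 16 lists outside their bar, from the pancreas list at -0.99 to Hox groups 10 to 13 at 0.51.

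Transcript tables gave the same leading isoform in both libraries for 7455 of 8043 genes with at least 2 annotated transcripts and a TPM of at least 5, or 92.7% (95% Wilson interval 92.1 to 93.2%). Pkm-201 held 90.7 ± 0.849% of the output of the pyruvate kinase gene Pkm, and Pkm-202 9.32 ± 0.849%. Hnf4a was split between Hnf4a-202 (74.4 ± 0.523%) and Hnf4a-205 (25.3 ± 0.460%), although by posterior mean Hnf4a-202 held 51.6%, and Actn1 between Actn1-201 (64.5 ± 0.198%) and Actn1-202 (35.6 ± 0.198%). A single transcript held nearly all output of Vil1 (Vil1-201, 98.4 ± 0.0707%), Apoa1 (Apoa1-201, 98.6 ± 0.106%) and Tpm2 (Tpm2-203, 97.2 ± 0.438%). Cdx2, Epcam and Myl6 have 1 transcript each in the tables, so their 100% carries no information. Muscle-related Cald1 was led by Cald1-211 (44.9 ± 0.566%) and Tpm1 by Tpm1-213 (36.2 ± 0.771%). The leading transcripts of Kitl (Kitl-202, 73.2 ± 3.98%), Cd44 (Cd44-207, 58.1 ± 7.56%), Tcf7l2 (Tcf7l2-209, 38.4 ± 0.601%), Numb (Numb-204, 37.3 ± 5.44%), Ctnnd1 (Ctnnd1-202, 37.6 ± 4.17%) and Fgfr2 (Fgfr2-217, 31.5 ± 0.919%) shared output with others. For Fn1, Igf2 and Ptbp1 the first and second transcripts lay within the spread of the libraries, at 37.8 ± 2.72% and 37.0 ± 0.0849%, 37.7 ± 2.51% and 37.2 ± 4.22%, and 35.0 ± 5.58% and 29.9 ± 5.38%.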

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

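The check of TPM scaling and the tests of epithelial amount, caudal gut and the split of the copies by direction were chosen after the results were seen. Limits for the other tests were set before their results were seen, but on patterns found in the same data.

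The entries named only by a number, outside every comparison above, held 56 counts in replicate 1 and 61 in replicate 2, above the 3 counts that an empty class allows. In replicate 1, 5 of the 26248 entries had any count and in replicate 2, 8, with 4 shared, and the highest entry held 48 and 49 counts. No group or control library exists against which to compare them.

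Pancreatic and adrenal genes were higher in replicate 1. The pancreas list's shift of -0.99, outside the random range of -0.09 to 0.09, is measured from the median gene. A factor common to all genes of a library, such as the authors' TPM scaling, largely cancels from such a shift and could not account for it. That follows from how the shift is computed and is not the outcome of a test. A larger piece of pancreas of the same make-up is argued against as the whole cause: acinar genes outside the fixed list lay further below 0 than islet genes (medians -0.77 and -0.20, exact permutation p = 0.026), as did the fixed members (-1.45 and -0.47, exact permutation p = 0.01), although gut endocrine cells also express some of the islet genes. As a part cause it stays open, since islet genes outside the fixed list also shifted, by -0.22 against a random range of -0.20 to 0.14. Adrenal cortex genes outside the fixed lists had a shift of -0.47, below the random range of -0.13 to 0.13 but short of the limit of -0.5 set beforehand, with Star at 7.45 and 0.930, Cyp11a1 at 18.4 and 7.83 and Mrap at 2.85 and 0.320 in replicates 1 and 2 beside broadly expressed members such as Fdx1 at 74.8 and 65.7, so adrenal tissue in pool 1 stays open as a candidate source. A different maturity or portion of pancreas in the pools may also remain, and no biological explanation was tested, since the design has 1 group.

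Enterocyte and goblet genes were also higher in replicate 1, the early enterocyte list by a shift of -0.32 and goblet genes by -0.36, while enteroendocrine genes (-0.09) stayed within their random range. Less epithelium in pool 2 is argued against as the whole cause, because early enterocyte genes lay below the epithelial regulators (medians of -0.30 and 0.01, permutation p = 2e-05, the smallest possible). The shifts of both lists had been seen before this test, so its p-value only restates them. Whether the regulators are also expressed outside the epithelium was not examined, but epithelial structure genes (-0.08) also shifted less than early enterocyte genes. As a part cause, less epithelium stays open, and the lists do not settle it. Epithelial structure genes shifted by -0.0751 (12 of 15 lower), just inside their random range of -0.0795 to 0.0860. Intestinal progenitor genes went the other way by 0.06 (4 of 15 lower), also within their range. Mesenchyme (0.15), Cajal (0.18) and enteric neuron genes (0.14) lay above their ranges. A later stage of pool 1 also stays open. For it, 23 late enterocyte genes outside the fixed lists had a shift of -0.11, below the random range of -0.07 to 0.08. The embryonic share of globin was also higher in replicate 2 (1.20% against 0.762%). The late enterocyte shift was smaller than those of early enterocyte genes (-0.32) and mature enzymes (-0.21) and close to that of epithelial structure genes (-0.08). It therefore cannot tell a later stage from less epithelium in pool 2. More caudal gut in pool 2 cannot be told apart, because only 4 caudal genes outside the fixed lists were detected (median shift 0.0231), and the fixed lists went both ways, with Hox groups 10 to 13 at 0.51, proximal genes at -0.14 and distal genes at -0.10, the last 2 within their random ranges (proximal genes lay outside at -0.15 under TMM and DESeq2's size factors and at -0.16 under spike-in scaling). The labels give both pools the same age, so the design has no group that tests the stage itself.

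Genes over 2-fold apart often lie in copy families. Of the 82 such genes, 46.3% had a credibility interval more than 2-fold wide in at least 1 library (95% Wilson interval 36.0 to 57.1%), against 1.22% of other genes at the same expression. For the 20 genes higher in replicate 2 the share was 85% (64.0 to 94.8%), which fits reads split differently between near-identical copies. For the 62 lower ones it was 33.9% (23.3 to 46.3%), and 26 of the 61 with a known sequence shared over 50% of their words with other genes, so copies do not account for most of that side. No biological explanation was tested here either.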

How the results depend on the processing

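Scaling to spike-ins, the restriction to protein-coding genes and every alternative for the count of genes over 2-fold apart were chosen after seeing the data. Of the 10 list comparisons, 4 passed the adjusted threshold, and none of the 4 changed direction under an alternative, while Hox groups 6 to 9 against 1 to 5 (-0.58 to 0.09) and epithelial regulators against liver (-0.03 to 1.30), which did not pass, went either way. With a pseudocount of 1, early enterocytes against mature enzymes (2.38) and smooth muscle against Cajal cells (2.56) passed, and the latter also with FPKM (2.64). Leaving out members under a TPM of 0.5 took Hox groups 6 to 9 against 10 to 13 (0.96) out of the calls. On each library alone the latter ranged from 1.90 to 2.18 and smooth muscle against Cajal cells from 2.52 to 2.78, each called only on replicate 1. Proximal against distal genes could not be run without shared members, since 1 proximal gene remained. The median absolute ratio of 0.11 became 0.12 with a pseudocount of 0.1, 0.10 for genes at a TPM of 5 or more, 0.0274 without a filter, 0.10 with TMM, 0.10 with DESeq2's size factors, 0.11 with posterior mean TPM, 0.10 for protein-coding genes and 0.26 with spike-in scaling, which moves the median of all genes to 0.25. The 104 genes over 2-fold apart became 56 at a TPM of 5 or more, 59 for protein-coding genes and 365 without a filter, and 72 to 155 under the other alternatives. By counts in place of TPM, the class shares were 1.96% for spike-ins, 0.734% for globin, 0.108% for histones, 1.44% for mitochondrial messengers, 2.86% for ribosomal proteins and 92.3% for other genes. By posterior means, ribosomal RNA came to 0.714%, globin to 2.08% and other genes to 82.9%. Isoform agreement was 91.0% at a gene TPM of 1 and 94.5% at 20. Lists outside the random range numbered 15 to 17 under the alternatives, of which 14 to 16 were among the original 16. Scalings by a common factor are largely cancelled in these shifts, which subtract the median gene. Of the values for single genes and lists, 898 kept their call or stayed within 1 SD, 46 gene values moved further with posterior mean TPM, 8 list shifts entered the calls and 4 left them. A mean of 2 libraries moves by less than its SD when either is left out, whatever the data. The 898 include 216 gene values without replicate 1 and 216 without replicate 2, which could not have moved. With posterior mean TPM, 170 gene values stayed within 1 SD beside the 46 that moved. Depth limits genes below about 3 counts, and with 2 libraries an SD is itself uncertain; the causes of these changes were not tested.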

Other observations

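The genes named in this part were chosen after the results were seen. Of 10 acinar genes outside the fixed list, 8 lay lower in replicate 2 relative to the median gene, with Spink1 (628 and 485) and Rnf186 (81.4 and 66.6) differing least among these 8. Nr5a2 (8.58 and 8.73) and Dbpht2 (1.90 and 2.08) did not lie lower. Picked for their large differences, the exocrine genes that follow were higher in replicate 1. Cel and Cpb1 among them belong to the 10 acinar genes just described, so they add no separate evidence. Colipase, Clps, was at 2798 and 910.0 in replicates 1 and 2, the lipase-related Pnliprp1 at 2507 and 1124, the bile salt lipase gene Cel at 353 and 132 and Cpb1 at 76.5 and 22.7. Rnase1 stood at 73.7 and 23.4 and Reg1 at 54.0 and 23.4. Islet genes differed less, with Ins2 at 383 and 228, Ins1 at 49.7 and 35.5 and Iapp at 63.3 and 45.3.

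Brush border and transport genes of late enterocytes outside the fixed lists were already expressed at E15.5, 23 of 24 at a TPM of 1 or more in either library. Prap1 stood at 497 and 408, Smim24 at 239 and 197, Apoc2 at 216 and 139 and the microvillar cadherin genes Cdhr5 and Cdhr2 at 69.6 and 55.1 and 30.9 and 27.0. Of the 23, 19 lay lower in replicate 2 relative to the median gene.

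Over 20 spike-ins with at least 1000 counts in both, the log2 ratio of TPM had a median of -0.26, an SD of 0.23 and a range from -0.83 to 0.03. Over 7201 genes with at least 1000 counts the SD was 0.17, without matching on depth. At mean counts of 300 to 1000 the SD was 0.27 for genes and 0.21 for spike-ins, while the median absolute deviation was 0.13 and 0.15, so the order depends on the measure there.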
